A study of Streptococcus thermophilus with 3 samples.

How the data were processed

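The series holds 3 arrays of Streptococcus thermophilus, a lactic acid bacterium used in yogurt and cheese. On each array, cDNA of wild-type strain LMD-9 and of strain CB003, the comX knockout, competed for the same spots. The comX gene codes for the alternative sigma factor that directs RNA polymerase to the late competence genes of streptococci. Per the labels' protocols, both strains were grown for 16 h at 37 °C in M17 broth with 1% lactose, washed, diluted 30-fold in a chemically defined medium with 1% lactose and harvested at an OD600 of 0.4. Per the labels, cDNA was made from 10 microg of total RNA and labelled with Alexa Fluor 555 (scanned as green) or Alexa Fluor 647 (scanned as red).

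The deposited scanner files give, per the file headers, intensity values from Agilent Feature Extraction 9.1.3.1; the submitters' processing notes name version 9.1. They hold the mean brightness of each spot, its local background, flags for outliers and saturation, processed intensity values that the software had background-subtracted and dye-normalized, and a log10 ratio of red over green. The authors' table for the whole series holds log10 ratios. Against the scanner's log10 ratio, its columns correlated at -1 for arrays 1 and 2 and at 1 for array 3. By the dyes in the labels this gives knockout over wild type on every array, the direction used here. The medians of its columns were 0.0267, 0.0200 and 0.0168 on the log10 scale. Its scale and centring were therefore settled by this comparison, and its direction by the comparison together with the dyes in the labels.

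Array 1 and array 3 carried the same pair of clones with the dyes exchanged and were counted as 1 biological replicate. Array 2 carried the second pair of clones, with the dyes placed as on array 1. Arrays 2 and 3 shared a slide and a scan day, and array 1 was alone on another slide. The deposited array names probes only by locus tag, which is a number for each gene. No gene table or genome was used here, so gene names, products, coordinates and strands are not given. The planned readout of comX itself and the planned tests of gene lists fixed in advance, late competence genes among them, could therefore not be made.

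Mean signals were corrected for background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3. Control spots and spots flagged as outliers had weight 0 in the loess, and flagged spots were left out of the averages. Spots of a probe were averaged, and then the probes of a gene. A probe was kept when at least 0.5 of its spots were well above background in the knockout channel, or in the wild-type channel, on all 3 arrays. This kept 8402 of 8410 probes, and the other 8 were left out because of outlier flags. Every gene's log2(knockout/wild type) was averaged within the biological replicate, and the 2 replicate values were tested against 0 with lmFit and eBayes. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. The fit had 1 residual degree of freedom and 7.94 prior degrees of freedom per gene. Standard errors of single genes are limma's moderated ones.

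The genes named were to be the 12 lowest and the 12 highest past the threshold with the same sign on all 3 arrays. Because the files do not pair locus tags with gene names, only the first 2 of each direction are named, and other genes are described by their number and values. These rules, the fit and 14 of the 16 alternatives that gave values were fixed before the data were examined. The alternatives covered the background correction, the normalization, the filter on dim probes, the summary of probes, the authors' table, the dye effect, left-out arrays and replicates, and the eBayes settings. Removal of a trend on probe GC content and a normexp offset of 0 were added after the data had been seen.

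Runs of called genes with consecutive locus tags were compared with 1000 shuffled orders. The fit was tested on simulated ratios for 1923 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 87% of the former and 100% of the latter, and 19 of its 206 calls (9.22%) were unchanged genes. This share was above the adjusted p threshold of 0.05, so the simulation did not show that the fit holds that rate. In the data, the difference between the replicates correlated at r = 0.695 over adjacent tags. How the fit behaves under such shared error was not tested separately. Probe sequences were translated with Biopython 1.88 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

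Median signals of the probes were 1722 (knockout) and 2096 (wild type) on array 1, 3637 and 1150 on array 2, and 5748 and 5898 on array 3. The 77 negative control spots had medians between 52.8 and 61.4. No probe spot was saturated. Duplicate spots of a probe differed by an SD of 0.0438 to 0.0543 (log2). The number of arrays limits the precision.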

Results

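Transcript levels were measured in wild-type Streptococcus thermophilus LMD-9 and in its comX knockout, strain CB003, during growth in chemically defined medium with lactose. Each of the 3 two-colour arrays set 1 knockout culture against 1 wild-type culture, with 15208 probe spots for 1923 locus tags. Of these tags, 1448 were covered by 5 probes and 114 by a single probe. The design gave n = 2 biological replicates, replicate 1 being the mean of an array and its dye swap. All 8402 probes kept were well above background in both strains on all 3 arrays. The lowest 1% of probe spots had knockout signals up to 166, 378 and 871 on arrays 1, 2 and 3. Negative control medians in that channel were 61.4, 56.6 and 56.5. Being well above background therefore did not separate expressed genes from silent ones.

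The orientation of the arrays was checked first. Before their signs were turned, array 1 and its dye swap correlated at r = -0.891 across genes, as reversed dyes require. After turning, r was 0.891 between these arrays (Spearman's rho 0.613), 0.780 between arrays 1 and 2 (rho 0.324) and 0.726 between arrays 2 and 3 (rho 0.423). These correlations run across genes, which are not independent replicates. They would be the same if the strains were exchanged on all arrays, so the direction rests on the labels. The level of comX itself was not read out, because the files do not pair locus tags with gene names.

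The comparison of the strains asks which transcripts depend on comX in this medium. Loss of comX lowered 118 of 1923 genes and raised 53 (limma, adjusted p under 0.05, n = 2). Falls were deeper than rises. The genes that fell had a median log2 ratio of -2.16 (4.46-fold), and 64 of them fell at least 4-fold, 20 at least 16-fold and 8 at least 64-fold. The genes that rose had a median log2 ratio of 1.35 (2.55-fold), and 11 of them rose at least 4-fold. The median over all genes was -0.02. Every one of the 171 genes had the same sign on all 3 arrays. Of the 156 that had 3 or more probes, 156 had every probe in the direction of the gene.

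STER_1836 fell the furthest, with a log2 ratio of -7.31 ± 0.27 (SE, n = 2), or 159-fold (limma adjusted p = 6.66e-07). Its log2 ratios were -9.41, -6.84 and -6.17 on arrays 1, 2 and 3, so its size differed between arrays although its direction did not. Its signal in the wild type was 159600 on array 1, where the knockout gave 209.3. On array 2 the knockout gave 1488 against 53390 in the wild type, and on array 3 it gave 3330 against 172600. These signals are from before normalization. The 4 probes of the gene lay between -7.80 and -6.98 in the mean of the replicates. The lowest of them, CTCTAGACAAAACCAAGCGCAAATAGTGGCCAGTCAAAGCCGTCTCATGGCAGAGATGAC, gave -7.80. STER_1838 fell nearly as far, with a log2 ratio of -7.22 ± 0.33 (SE, n = 2), or 150-fold (limma adjusted p = 1.18e-06). Its values were -9.58, -6.49 and -6.35 on the 3 arrays. Before normalization its knockout signal was 143 on array 1, within the lowest 1% of probe spots there (up to 166). The value of -9.58 therefore rests on a dim signal. On array 2 the knockout gave 1119 against 23290 in the wild type, and on array 3 it gave 2188 against 116000.

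STER_0317 rose the most, with a log2 ratio of 2.98 ± 0.38 (SE, n = 2), or 7.89-fold (limma adjusted p = 0.000732). STER_0318 followed with 2.94 ± 0.41 (SE, n = 2), or 7.68-fold (limma adjusted p = 0.00138). Both rose further in replicate 2, with log2 ratios of 3.91 and 3.99, than in replicate 1, with 2.05 and 1.89. The 5 probes of STER_0317 lay between 2.91 and 3.07. The highest, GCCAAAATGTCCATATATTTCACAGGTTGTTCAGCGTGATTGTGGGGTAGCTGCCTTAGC, gave 3.07.

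**Figure D1:**
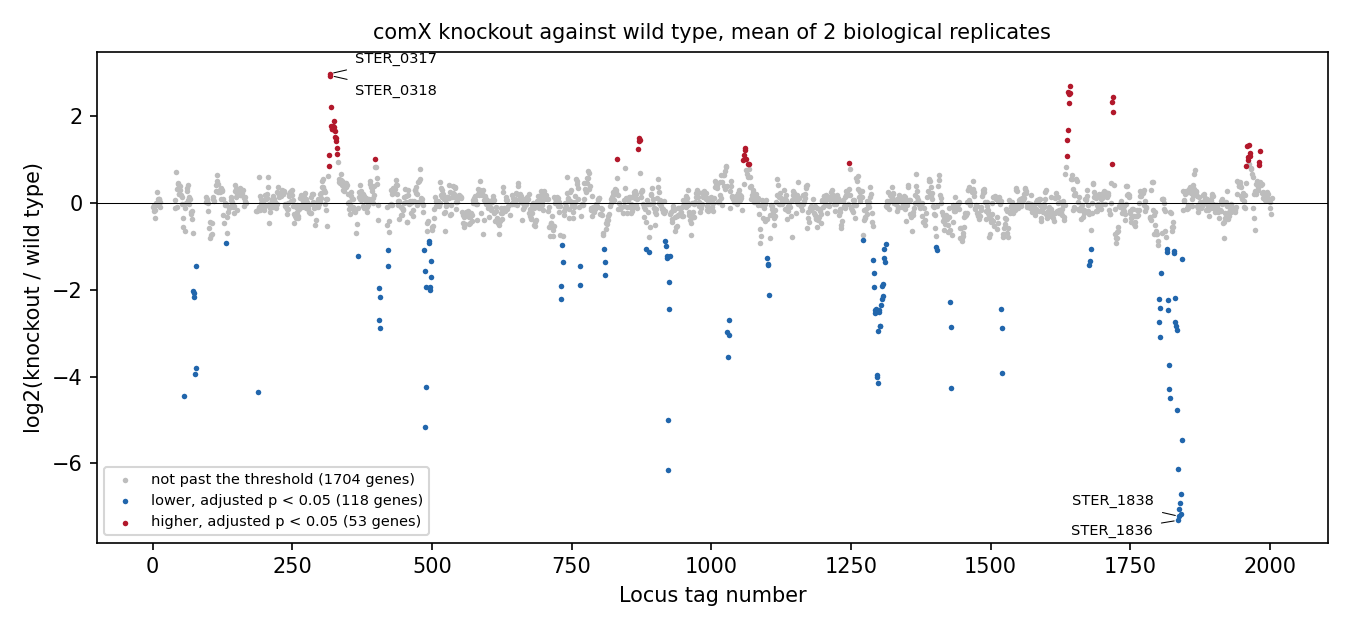
Mean log2(knockout/wild type) of 2 biological replicates for each gene with a numbered locus tag, against that number. Points in blue are the 118 genes lower and points in red the 53 genes higher at an adjusted p under 0.05; most of them stand in narrow groups along the axis, the deepest at STER_1836 and STER_1838.

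The changed genes stood side by side on the map. Of the 171 genes, 151 lay in 24 runs of 3 or more consecutive locus tags that all changed the same way, 16 runs of falling genes and 8 of rising genes. Only 12 changed genes stood alone. In 1000 shuffled orders of the tags, at most 9 genes fell into such runs, and the longest run had 5 genes (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). The shuffles treat adjacent tags as independent, but the difference between the replicates also correlated over them (r = 0.695). This p therefore does not tell a shared response from shared error. The runs held 104 of the 118 lower genes and 47 of the 53 higher genes.

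The longest run held 23 genes that fell, with a mean log2 ratio of -2.31 ± 0.23 (SE over the 2 replicate means), or 4.96-fold. A run of 16 genes, to which STER_1836 and STER_1838 belong, fell the most of the long runs, with a mean of -4.56 ± 0.35, or 23.6-fold. A run of 9 genes had a mean of -2.34 ± 0.06 and reached -6.17 at its lowest gene. A run of 7 genes had a mean of -2.78 ± 0.51. Among rising genes, the run of STER_0317 and STER_0318 was the longest. Its 17 genes had a mean of 1.72 ± 0.59, or 3.30-fold, made of 1.14 in replicate 1 and 2.31 in replicate 2. A run of 8 genes rose by a mean of 2.10 ± 0.59, or 4.29-fold.

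**Figure D2:**
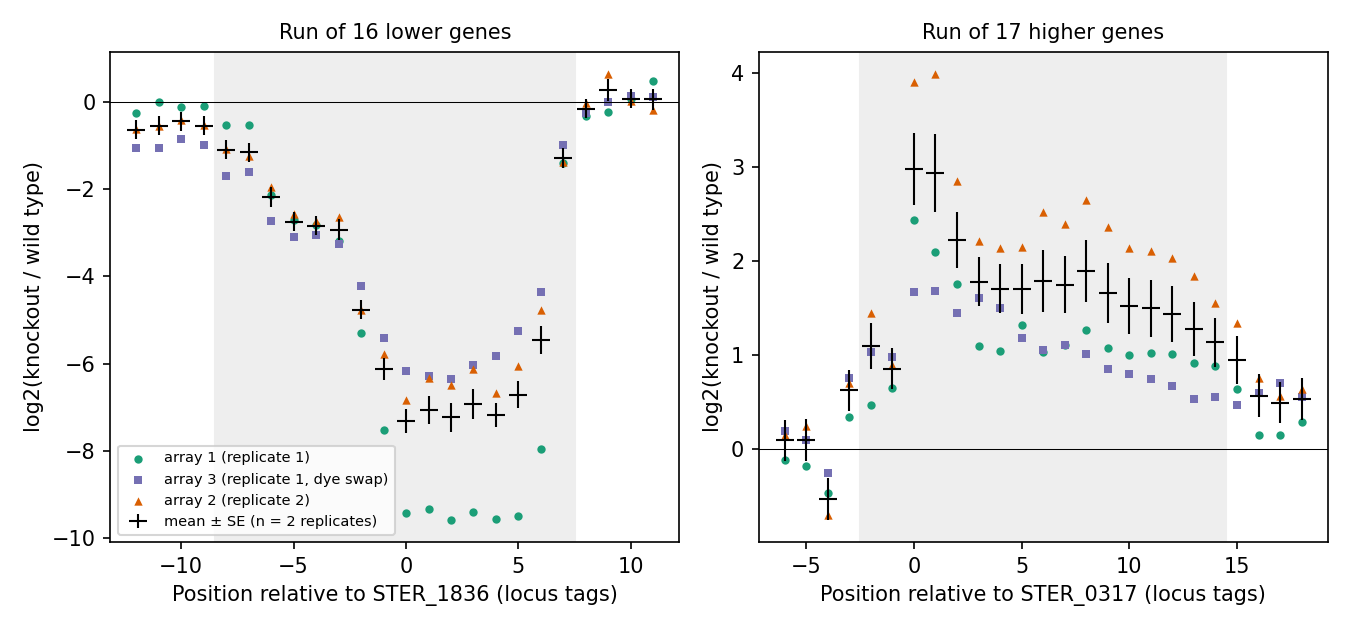
Log2(knockout/wild type) by position for the run of 16 lower genes around STER_1836 (left) and the run of 17 higher genes that holds STER_0317 (right), shaded, with 4 genes on either side. Bars are means ± SE over n = 2 replicates and symbols the 3 arrays. Array 1 lies lowest at the deepest genes of the left run, and array 2 highest across most of the right run.

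A count by size alone gave a like picture. With a mean change of at least 2-fold and the same sign on every array, 110 genes were lower and 43 higher, and all of them also passed the test. The number of higher genes by this count depended on the replicate, with 65 in replicate 2 alone (without replicate 1) and 31 in replicate 1 alone (without replicate 2). Within the slide that held arrays 2 and 3, the fit called 128 genes lower and 58 higher. Without background subtraction it called 99 lower and 24 higher, a split of 80.5% lower against 69.0%.

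The 2 replicates differed by an SD of 0.563 (log2) over the 1752 genes that did not pass, and correlated at r = 0.777 over all genes. The smallest change that passed in this fit was 0.85 on the log2 scale. The dye effect, estimated from array 1 and its swap, had an SD of 0.225 over genes and reached 2-fold for 17 genes. A dye effect of equal size on array 1 and its swap cancels in replicate 1, and the same effect would stay in replicate 2. Whether the size was equal cannot be checked, since this pair of clones has 1 array per dye orientation. Array 1 and its swap were also on different slides, so the estimate does not separate dye from slide.

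**Figure D3:**
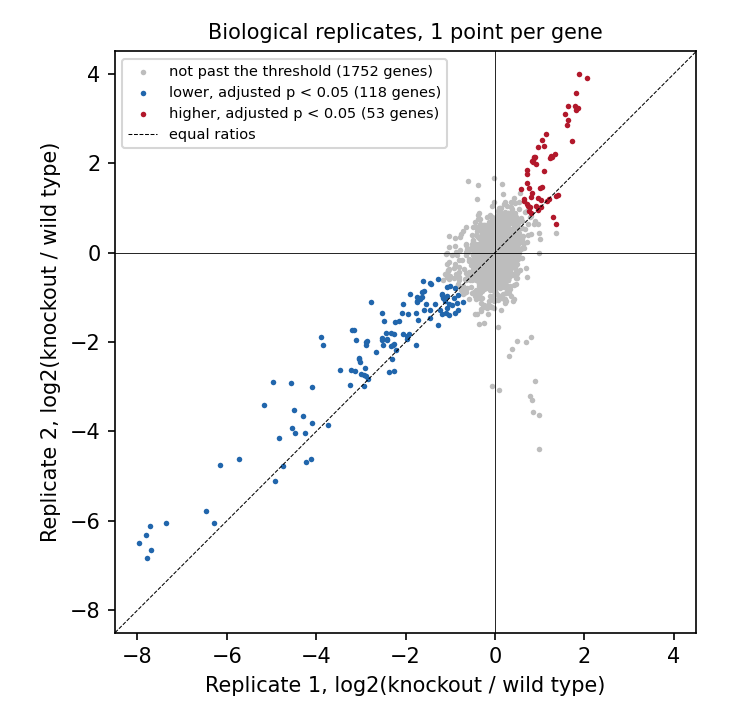
Log2(knockout/wild type) in replicate 1 (x axis, mean of arrays 1 and 3) against replicate 2 (y axis, array 2), 1 point per gene. The 118 lower genes (blue) and 53 higher genes (red) have the same sign in both replicates, with r = 0.777 over all 1923 genes; higher genes lie mostly above the dashed line of equal ratios.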

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

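The arrays carry 59 kinds of positive control probe that no comparison used. Besides the corner marker, 20 of them were well above background in both channels on all 3 arrays. The brightest, on 6 spots, gave median signals of 2116, 1303 and 2510 in the knockout channel and 1880, 1007 and 2700 in the wild-type channel of arrays 1, 2 and 3. The medians of the negative control spots per array and channel lay between 52.8 and 61.4. Whether control RNA was added is not given in the sources used here.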

How the results depend on the processing

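The removal of the GC trend and the normexp offset of 0 were chosen after the data had been seen. Over the 14 alternatives with a test, between 123 and 230 genes passed, against 171, and none of the 171 passed in the opposite direction. The count of higher genes fell to 24 without background subtraction, and all 123 genes called there were among the 171; the cause was not tested. The count of genes at least 2-fold higher ranged from 31 to 65 when a replicate was left out, and the count at least 2-fold lower from 126 to 152. These counts have no test, and they require the sign only on the arrays left. The log2 ratios of the 4 named genes kept direction and threshold in each of the alternatives with a test. With trend and robust set in eBayes, 163 genes were lower and 67 higher, sharing 165 with the 171. The authors' table gave 106 and 48, sharing 152. Without the dye-swap array the counts were 112 and 44, and with replicate 2 corrected for the dye effect 115 and 48. Both other filters on dim probes removed no gene and so test nothing. With the sign of replicate 2 turned, limma called 0 genes, and 1 had an unadjusted p under 0.05, against 318 in the data as labelled. That turn puts every change shared by the replicates into the residual error, so few calls follow by construction. The count therefore does not measure false calls. The fit of 3 arrays with an estimated correlation within the biological replicate was not run, since 3 arrays gave no estimate. No separate paired analysis was run, because the ratio within each array already pairs both strains and there is 1 comparison. The alternatives for comX and for gene lists were not run, since no list could be matched. All 8402 probes kept were well above background in both strains on all 3 arrays.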

Other observations

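Tests of spot position, of shared measurement error, of the gaps between replicates and arrays, and of fading along runs were chosen only after the pattern had been seen; those of shared probe sequence, GC content and the prepilin-like stretch were written before their results.

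Some locus tags that carry a letter before the number stood apart. The 14 tags with r, A or B had a median log2(knockout/wild type) of -0.24 on array 1, -2.92 on array 2 and 1.57 on array 3, and none passed the threshold. All 14 were lower in the knockout on array 2, and all 14 were higher on array 3. Their median log2(red/green) was above 0 on every array, at 0.24, 2.92 and 1.57. The 8 tags with r had median signals of 335800 in the red and 84448 in the green channel of array 1. On array 2 these were 174700 and 36449, and on array 3 193560 and 47834. After normalization their median log2(red/green) was 0.11, 3.25 and 2.02 on arrays 1, 2 and 3. The arrays thus differed more in the normalized ratios of these tags than in their signals. None of the 33 tags with t passed, and their median was -0.24.

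A hypothesis from the biology of competence was that genes of type IV pilin-like proteins, which build the DNA uptake pilus, fall without comX. Such proteins carry a conserved stretch near their start: glycine or alanine, phenylalanine, threonine, leucine, a leucine, isoleucine, valine, methionine or alanine, and glutamate. Of 8410 probes, 99.2% had an open frame as printed and 76.5% on the reverse strand, so the printed strand was read. The stretch was found in probes of 2 genes, and of none on the reverse strand. Their median log2 ratio was -7.12 (139-fold), and a one-sided permutation test with 100000 draws of genes gave p = 1e-05, the smallest it can give. Both lie in the run of STER_1836, so they are not independent and the p overstates the evidence. The result is consistent with the hypothesis, but rests on 2 genes and on a stretch that is short. Genes whose probes do not cover the start of the protein were not searched.

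The log2 ratios of adjacent locus tags correlated at r = 0.864 over 1824 pairs, against at most 0.098 in 1000 shuffled orders. The correlation was 0.716 at a distance of 2 tags, 0.401 at 5 and 0.179 at 10. Among genes with an unadjusted p above 0.2 it was 0.511, below the values for the difference between the replicates (r = 0.695) and for the dye effect (r = 0.678) over all adjacent tags. A shared change among genes not called was therefore not shown, and calls in a run are not independent of each other. Against spot position, touching spots of different genes correlated at no more than 0.00656 on any array. Only 0.763% of neighbouring called pairs had probes that share 20 bases or more, and r stayed at 0.862 after a trend on probe GC content was removed. At 2-fold, error shared by neighbours but differing between the replicates did not by itself give runs like those in the mean. In the mean of the replicates, 132 of 161 genes at 2-fold lay in runs of 3 or more. When the sign of replicate 2 was turned before averaging, 0 (0%) did, but only 17 genes reached 2-fold there. The 161 and the 17 include lettered tags, which cannot lie in a run. How many of the 17 were numbered was not counted, so few may have been able to form a run. Error common to both replicates is removed by that turn and was not tested. Transcription of neighbours from shared promoters is a candidate explanation and was not tested, since strands and gene spacing were not used here.

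A further hypothesis was that transcription runs on past the strongest gene of a run, so that the response fades to one side. In the 9 runs with 3 or more genes on the longer side, 91.2% of 261 gene pairs declined with distance from the strongest gene. This does not bear on the hypothesis, because the strongest gene was picked as the starting point and neighbouring genes are correlated, which gives a decline in any case. A symmetric spread would leave both sides alike, but the 3 genes on either side of the strongest differed by over 2 standard errors in 58.8% of the 17 runs of 4 or more genes, with the errors of the genes of a side taken as fully shared. These genes were the next in tag order, also across gaps in the numbering and past the end of a run. They were not always adjacent, so the share does not settle whether the spread was symmetric. Neither strand nor terminators were used here, so the hypothesis stays open.

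The median log2 ratio of the 53 genes that rose was 1.03 in replicate 1 and 1.82 in replicate 2, and 45 of them were higher in replicate 2. The 118 genes that fell also lay lower in replicate 1, with a median of -2.33 against -1.90 in replicate 2 and 93 of them lower in replicate 1, so the gap is not particular to the genes that rose. After correction of replicate 2 for the dye effect the median gap was still 0.784. This argues against a dye effect as estimated from arrays 1 and 3 as the whole source. The correction assumes the same effect on array 2, which was not tested. Array 2 also lay above array 3, on the same slide, by a median of 0.907. These arrays had opposite dyes and different clones. A slide effect on red over green would move their ratios apart, so this gap does not decide on the slide. A difference between the cultures or clones, an effect of the slide, or a dye effect particular to array 2 stays open and was not tested. Only 1 array stands for replicate 2.

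The 20 genes that fell at least 16-fold had a median log2 ratio of -6.24 on array 1, -4.76 on array 2 and -4.63 on array 3, although arrays 1 and 3 carried the same pair of clones. All 20 were lowest on array 1 against both others. Against one additive floor for all probes on array 3, 10.4% of its probe spots had a knockout signal under 0.5 times the median of these genes. A floor that differs between probes was not tested. Array 2, with the dyes of array 1, lay above it by a median of 1.52. Array 2 carried the other pair of clones on the other slide, so this gap does not exclude dye orientation. Array 3, the dye swap with the same clones, lay above array 1 by a median of 2.15. It differed from array 1 in both dye and slide. Arrays 2 and 3, on the other slide, were only 0.390 apart, as an effect of the slide or scan of array 1 would give. That slide holds 1 array here, so dye, slide, scan, hybridisation and RNA preparation cannot be told apart.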
